A study of Saccharomyces cerevisiae with 7 samples.

How the data were processed

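The study used 7 one-colour Affymetrix yeast arrays: 3 of control chemostat cultures, 2 with 10 g/l galacturonic acid and 2 with 0.23 g/l galactose. Groups were taken from the treatment given in the labels. For the galactose arrays 1 label field names galacturonic acid at that dose, while the title, the description and the treatment field name galactose, which was used. Replicate numbers within a group were given in deposit order and name an array only.

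Per the labels' protocols, the authors quenched culture broth in liquid nitrogen, extracted RNA with phenol and chloroform, made biotin-labelled cRNA by in vitro transcription and hybridised it to the arrays. Per the submitters' processing notes, GCOS 1.2 was used. The values deposited by the authors are intensity values per probe set on a linear scale, never negative, for 9335 probe sets. After leaving out the highest and lowest 2% of values, the mean of each array was 150.1 to one decimal, which was read from the deposited values, and the signal algorithm and its settings are not given in the sources used here. The median over probe sets ranged from 36.3 to 50.5 between arrays, and 31.1% to 33.8% of probe sets lay at or below an intensity of 12. No array file held values identical to another: at most 2.05% of probe sets had equal values on any pair of arrays.

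Of the probe sets, 60 are controls, 6504 have 1 gene in the platform annotation, 328 have several and 2443 are not listed. Apart from 2 probe sets in the closing paragraph, genes were named only from probe sets with 1 gene, and all 6504 matched the RefSeq table of assembly R64 by gene ID. No genome build is named in the sources used here, so no coordinates are given, and coding lengths come from that table. For genes with more than 1 probe set (315 genes), the probe set with the highest mean over the arrays was used. This left 5656 genes, of which 5220 lay above the floor on at least 2 arrays and were tested, and 436 did not.

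Values were raised to a floor of 12 and taken as log2. One linear model with a mean per group was fitted over all 7 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, 4 residual degrees of freedom), and 3 comparisons were tested with Benjamini-Hochberg adjustment over the 5220 genes at a threshold of 0.05. Log2 differences are given with the standard error of that fit, and intensities as mean ± SD over the arrays of a group without the floor. Where all arrays of the dimmer group lay at or below the floor, the fold is a lower bound against the floor. A series of 34 gene lists, fixed from textbook knowledge before the data were examined, was tested with limma's camera (preset correlation 0.01), with an estimated correlation and with fry as alternatives, adjusted over the 34 lists.

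The genes named were chosen by a rule set before the data were examined: for each comparison, the 10 largest rises and falls among genes past the threshold whose groups did not overlap, every measured member of the Gal4 target and hexose transporter lists, and up to 2 rises and 2 falls past the threshold of every other list described, or its member with the smallest p. Other genes named as members of a count, and the remaining mating genes, were added after their values were seen. Near-identical paralogs are given as uncertain.

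Fitting was tested on simulated data with 200 changed genes among the 5220, drawn with the spread of each group. The changed genes were taken only from those with a control level well above the floor, so the recovered shares do not cover dim genes. Noise was drawn independently for each gene. For galacturonic acid against control, 12%, 86%, 100% and 100% of 2-, 4-, 8- and 16-fold changes were recovered with 1 false call. For galactose against control 30%, 82%, 96% and 100% were recovered with 78 false calls, and for galacturonic acid against galactose 18%, 72%, 94% and 96% with 42 false calls. The noise had a relative spread of 0.70 for control, 0.48 for galacturonic acid and 1.51 for galactose, while the fit assumes 1 spread per gene for all groups. The fit of the real arrays makes the same assumption. No run with equal spread was made, so its part in these false calls was not tested. A further 20 genes were shifted by 1 on the log2 scale to test camera, and 4, 7 and 3 of them are among the 154, 239 and 185 calls. Unchanged groups, also with the spread of each group, were simulated 100 times to find what shared arrays give by chance, and gave means of 0, 1.21 and 0.2 calls in these 3 comparisons.

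Alternatives fixed beforehand were quantile normalisation, scaling to the 75th percentile, floors of 1 and 50, log2 of the value plus 16 without a floor, no filter on low genes, a filter at the median level, the mean of all probe sets of a gene, every probe set on its own, no intensity trend, array weights, a fit of only the groups compared, a replicate block, stricter thresholds and leaving out each array. A count over genes of at least 500 bases was added after the 3'/5' signals were seen, as was the range of shifts from control over the probe sets of a gene, taken on each array for the 253 genes with several probe sets above the floor. Figures were drawn with matplotlib 3.10.9. The precision of every value is limited by the number of arrays, 2 or 3 per group.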

Results

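Transcript levels were measured on 7 one-colour Affymetrix arrays hybridised with RNA from chemostat cultures of CEN.PK113-7D, a haploid laboratory strain of Saccharomyces cerevisiae of mating type a. A chemostat holds cells at a set growth rate by feeding one limiting nutrient. All 7 cultures were aerobic and glucose-limited, with 7.5 g/l glucose in the feed, a dilution rate of 0.1 per h, pH 3.5 and 30 °C. The control group had 3 arrays with no further addition. A group of 2 arrays came from cultures fed 10 g/l galacturonic acid, the main sugar acid of pectin. A further 2 arrays came from cultures fed 0.23 g/l galactose. The samples carried different culture codes, and p-values measured only the spread between these arrays. The deposited values were linear intensities scaled so that the trimmed mean of each array was about 150.1, and the number of arrays limits the precision of each value.

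The arrays were not equally alike. Across the 5220 genes tested, which are not independent replicates, Pearson's r of log2 intensity was 0.951 to 0.973 between control arrays, 0.976 between the galacturonic acid arrays and 0.818 between the galactose arrays. The median SD between arrays of a group was 0.30 on the log2 scale for control, 0.17 for galacturonic acid and 0.52 for galactose. Control probe sets on the array read the 3' and 5' ends of 2 yeast transcripts. For ACT1 (actin), the 3'/5' ratio was 1.07 to 1.34 on the 5 control and galacturonic acid arrays, 19.8 on galactose array 1 and 306 on galactose array 2. For SPT15 (TATA-binding protein) it was 1.66 to 2.75 on those 5 arrays, 2.76 on galactose array 1 and 124 on galactose array 2. No floor was applied to these ratios. The 5' intensities behind 306 and 124 were 10.5 and 4.1, below the floor of 12, so the sizes of these ratios are uncertain. On galactose array 2 the 618 genes with a coding length under 500 bases had a median log2 value 0.69 above the control mean, against 0.00159 for the 4602 longer genes. Probe sets of one gene also disagreed on the galactose arrays. Of 253 genes with several tested probe sets, the shifts from control spanned over 2 log2 units in 60 on galactose array 1 and 131 on galactose array 2, against 2 to 6 on the other 5 arrays. For FAS1 and FAS2, the fatty acid synthase subunits, with 8 probe sets each and chosen after their values were seen, 5 and 3 were lower with galactose than in control in a fit of every probe set, while the probe set with the highest mean of each, the one used below, had differences of 0.37 and -0.80 that did not pass.

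**Figure D1:**
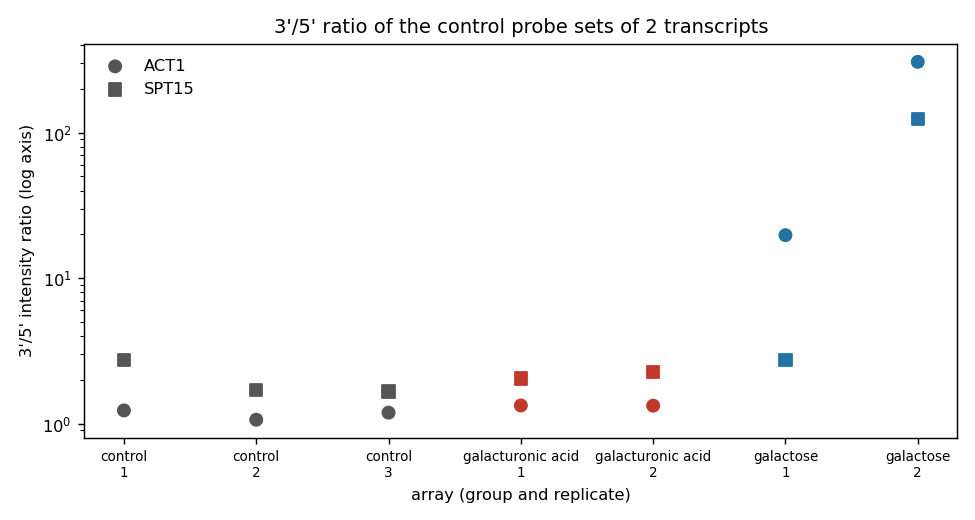
Ratio of 3' to 5' intensity (log axis) for the control probe sets of ACT1 (circles) and SPT15 (squares) on each of the 7 arrays, one point per array, grey for control, red for galacturonic acid and blue for galactose. ACT1 stood at 19.8 and 306 on the galactose arrays and at 1.34 or below on the others. On galactose array 2 the 5' intensities, 10.5 for ACT1 and 4.1 for SPT15, lay below the floor of 12, which was not applied here.

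The study asked how galacturonic acid affects yeast and whether hexose transporters are involved, so the first comparison set the galacturonic acid cultures against control. The structural genes of galactose use were among the largest rises. All 3 control arrays read GAL2 (YLR081W, the galactose permease) below the floor of 12 intensity units, with a mean of 7.83 ± 0.80 (SD, n = 3), while the galacturonic acid arrays read 282 ± 25.2 (SD, n = 2), at least 23.4-fold higher (adjusted p = 0.000489). GAL10 (YBR019C, the epimerase) was at least 9.99-fold higher, GAL7 (YBR018C, the uridylyltransferase) at least 9.19-fold and GAL1 (YBR020W, galactokinase) at least 7.33-fold, with adjusted p of 0.00721, 0.00437 and 0.00488. Each of these lower bounds set the galacturonic acid mean against the floor. Of the 10 measured targets of the activator Gal4, these 4 rose, and 5 passed when adjusted over the list alone. The other 6 did not pass: log2 differences were 1.26 ± 0.38 (SE) for GAL3, 0.90 ± 0.44 for GAL80, 0.66 ± 0.44 for GCY1, 1.57 ± 0.71 for FUR4, 0.70 ± 0.38 for MTH1 and -0.45 ± 0.40 for PCL10. The list as a whole shifted upward with a mean log2 difference of 1.86 (camera adjusted p = 4.29e-09), and the adjusted p was 0.092 with an estimated correlation.

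**Figure D2:**
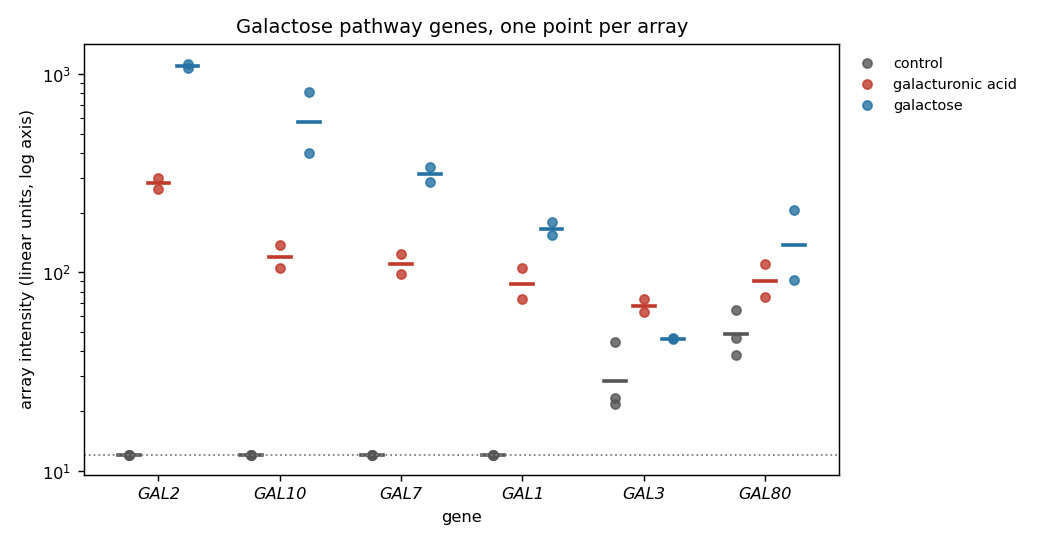
Array intensity (linear units on a log axis) of 6 galactose pathway genes, one point per array, with bars at the group means on the log scale and values below the floor of 12 (dotted line) drawn at it. GAL2, GAL10, GAL7 and GAL1 lay at the floor on all 3 control arrays, and the galacturonic acid arrays lay between control and galactose for each of these 4 genes.

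None of the 10 tested genes of the hexose transporter and glucose sensor list passed the threshold. That list does not hold the galactose permease gene GAL2, given above with the Gal4 targets. The low-affinity transporter HXT3 had a log2 difference of 1.58 ± 0.42 (SE, adjusted p = 0.132) and HXT4 of 2.49 ± 1.02 (adjusted p = 0.363), while HXT5 was at -1.70 ± 0.54 (adjusted p = 0.207). The high-affinity transporters HXT6 and HXT7, whose near-identical sequences cannot be separated with certainty by their probes, read 3410 ± 264 and 2938 ± 165 (SD, n = 2) with galacturonic acid against 3736 ± 464 and 3460 ± 402 (SD, n = 3) in control. Their log2 differences were -0.13 ± 0.28 and -0.23 ± 0.28 (SE). Differences for HXT2, SNF3 and RGT2 were 0.08, -0.09 and -0.20. HXT1 and HXT8, at -0.04 and -0.12, each had 2 of 3 control arrays at the floor, and HXT1 also 1 of 2 galacturonic acid arrays, so the floor limits both values. The list mean was 0.16 and its median -0.11, with an adjusted p of 0.958. HXT10 and HXT14 were measured but stayed at the floor on too many arrays to be tested. Only 12 of the 19 listed genes were measured. HXT9, HXT11, HXT12, HXT13, HXT15, HXT16 and HXT17 had no probe set listed for 1 gene alone, so they entered no gene-level fit. Whether probe sets listed for several genes read them was not examined.

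The MATa-specific and mating response lists were higher with galacturonic acid, with part of their members past the threshold. Of the 7 genes that only MATa cells express, MFA1, MFA2, ASG7 and AGA2 rose, and all 7 passed when adjusted over the list alone. MFA1 (YDR461W), a precursor of the a-factor pheromone, was at 3348 ± 692 (SD, n = 2) against 816 ± 455 (SD, n = 3), and AGA2 (YGL032C), a subunit of a-agglutinin, was 5.05-fold higher (log2 2.34 ± 0.41 SE, adjusted p = 0.0313). STE2 and BAR1, the alpha-factor receptor and the protease that degrades alpha-factor, had larger mean differences than some genes that passed, 2.16 ± 0.79 and 2.65 ± 0.65 (SE), with adjusted p of 0.298 and 0.102. Of 12 genes of the haploid mating response, PRM1, SST2, AGA1 and FUS1 rose, by log2 differences of 2.80, 2.75, 2.67 and 2.41, FIG1 rose by at least 1.64 on that scale from a level below the floor on all 3 control arrays, and 6 passed over the list alone. The other 7 did not pass: FAR1 was at 1.96, STE3 at 1.55, FUS3 at 1.38, STE12 at 0.31, STE4 at 0.27, GPA1 at 0.23 and STE18 at -0.08. PRM1 and FIG1 encode membrane proteins of mating cells and SST2 a regulator that dampens pheromone signalling. The mean log2 difference was 1.99 for the MATa list and 1.49 for the mating response list (camera adjusted p = 5.86e-09 and 3.36e-08, with an estimated correlation adjusted p = 0.113 and 0.235), and the mating response call was also lost under the filter at the median level. MF(ALPHA)1 (YPL187W), the alpha-factor precursor normally expressed in MATalpha cells, was 28.1-fold higher, at 879 ± 47.9 (SD, n = 2) against 33.1 ± 12.7 (SD, n = 3), with an adjusted p of 0.0365, a call lost without a filter on low genes (adjusted p = 0.144) and without any one control or galacturonic acid array. Of the other tested MATalpha-specific genes, STE3, which the mating response list also holds, was at 1.55 ± 0.51 (SE, adjusted p = 0.219) and SAG1 at 0.22 ± 0.35 (adjusted p = 0.877), and the list of 3 tested genes had a camera adjusted p of 0.0178, against an adjusted p of 0.247 with an estimated correlation. That call was also lost with fry, without a filter and without galacturonic acid array 2, where the list mean was 2.07.

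**Figure D3:**
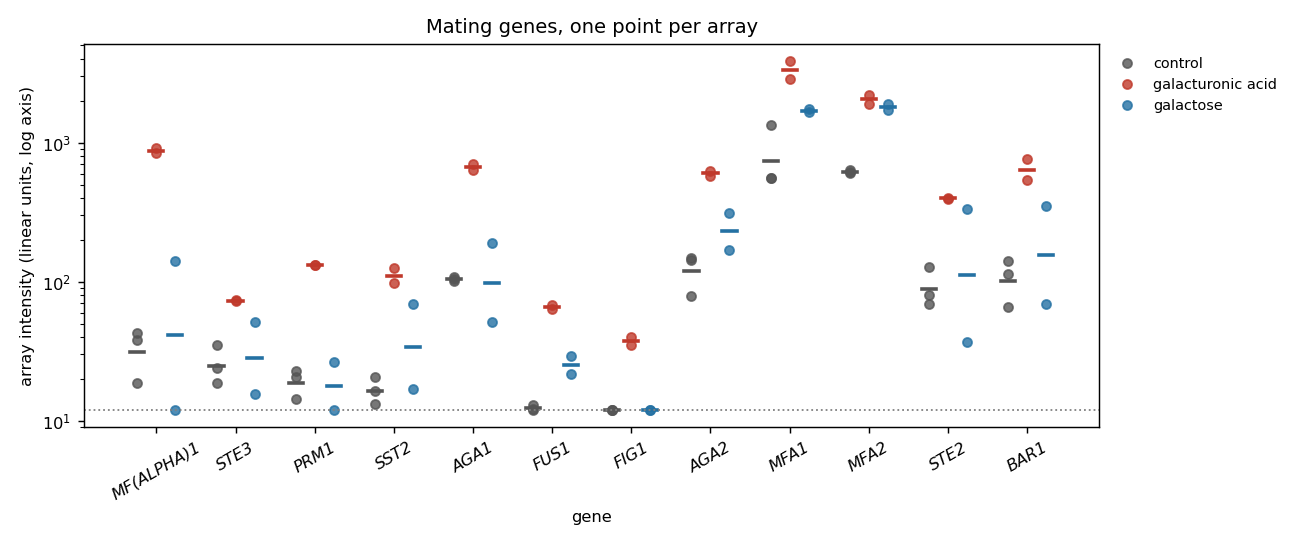
Array intensity (linear units on a log axis) of 12 mating genes, one point per array, with bars at the group means on the log scale and the floor of 12 as a dotted line. Both galacturonic acid arrays lay above all 3 control arrays for each gene drawn, and MF(ALPHA)1 showed the widest gap, 879 against 33.1 on average.

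Genes of general stress protection and of peroxisomal fatty acid breakdown were lower as lists with galacturonic acid. Of 30 general stress genes controlled by Msn2 and Msn4, 6 fell (17 when adjusted over the list alone, and 11 over all genes without galactose array 1 or without array 2) and none rose. They were RTN2, MSC1, GND2, DCS2, SOL4 and PNC1, with log2 differences from -3.11 to -1.25, and the list mean was -1.17 (camera adjusted p = 6.97e-14, with an estimated correlation adjusted p = 0.247). Of 17 peroxisomal beta-oxidation genes, PXA1, ECI1, CTA1 and IDP3 fell, with log2 differences of -2.41, -2.31, -1.98 and -1.91, where PXA1 encodes part of the peroxisomal fatty acid importer. The mean of that list was -1.05 (camera adjusted p = 6.67e-08, with an estimated correlation adjusted p = 0.235). In the list of gluconeogenic, glyoxylate and C2 genes, which did not pass, 3 of 22 members were lower and 1 was higher. The acetate transporter gene ADY2 (YCR010C) was 19.9-fold lower, at 21.8 ± 15.0 (SD, n = 2, with 1 of 2 arrays at the floor) against 424 ± 216 (SD, n = 3). The lactate permease gene JEN1 and ADH2, the ethanol-consuming alcohol dehydrogenase, fell, with log2 differences of -2.03 and -2.59. Without galacturonic acid array 1 or 2 the difference was -3.60 or -5.03 for ADY2 and -1.67 or -3.50 for ADH2. CIT2, the peroxisomal citrate synthase of the same list, rose 4.68-fold, and the list had a mean of -0.41 (adjusted p = 0.144). The ergosterol list had a mean of -0.46 (camera adjusted p = 0.0106, with an estimated correlation adjusted p = 0.617, lost also with fry), with no member past the threshold over all genes, 4 lower over the list alone, and 6 lower over all genes without galactose array 1 or without array 2. ERG5 had the smallest p, at -1.42 ± 0.30 (SE, adjusted p = 0.0538).

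**Figure D4:**
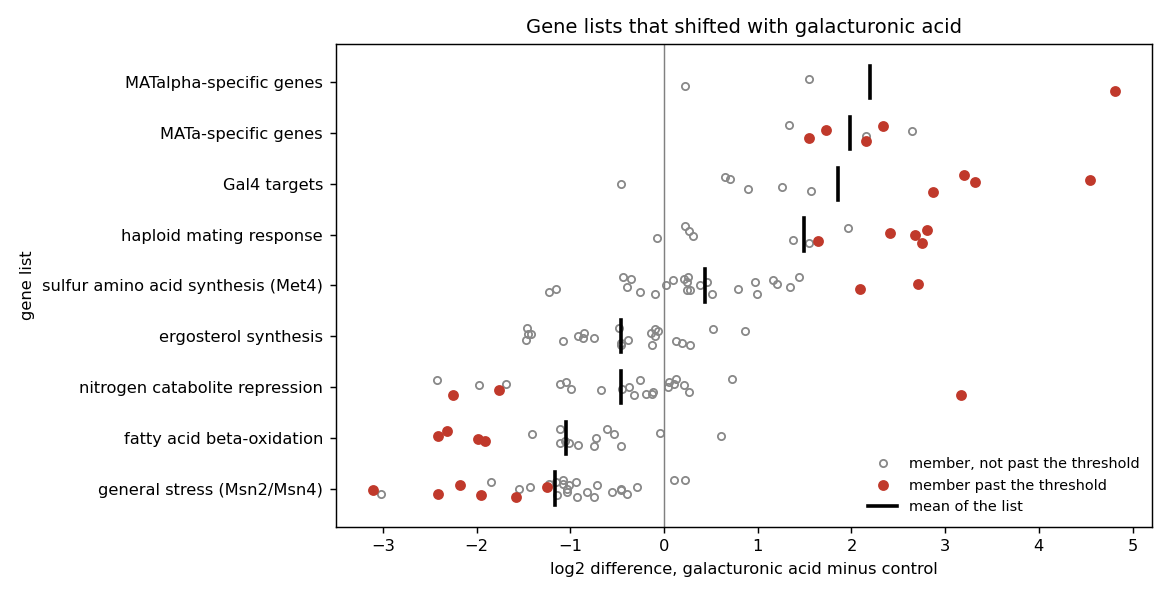
Log2 difference, galacturonic acid minus control, of every tested member of the 9 gene lists that passed the camera test, with filled red points for members past the threshold, open points for the others and a black bar at each list's mean. General stress genes averaged -1.17 and MATa-specific genes 1.99, and nitrogen catabolite genes moved both ways.

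The other largest changes lay outside these groups. DAK2 (YFL053W, dihydroxyacetone kinase) showed the largest rise on the floored values, 41.7-fold, from 11.4 ± 1.37 (SD, n = 3, with 2 of 3 arrays at the floor) to 514 ± 42.0 (SD, n = 2), with an adjusted p of 0.000106. The folds of the GAL genes are lower bounds, so their rank against DAK2 is not fixed. TPO2, a polyamine exporter gene of the Haa1 weak acid regulon, rose 13.5-fold, while GRE1 of the same list fell by 3.18 on the log2 scale, and the list of 15 tested weak acid genes had a mean of 0.02 (adjusted p = 0.952). SFG1, a regulator of filamentous growth, rose 11.2-fold. The largest falls included YDL218W (26.1-fold, with 1 of 2 galacturonic acid arrays at the floor), the cell wall mannoprotein gene HPF1 (25.1-fold, from 4333 ± 766 to 171 ± 26.2), FAT3 (18.5-fold), the proton ATPase isoform PMA2 (15.2-fold), YNL194C (15.0-fold), SPG4 (11.1-fold), SPS100 (10.4-fold), the water channel AQY1 (at least 10.3-fold) and the translation elongation factor isoform HEF3 (9.93-fold). In the nitrogen catabolite list the amino acid permease AGP1 rose 8.99-fold, whereas the general permease GAP1 and the proline oxidase PUT1 fell, with log2 differences of -2.25 and -1.76. The mean of that list was -0.46 (camera adjusted p = 0.0215, with an estimated correlation adjusted p = 0.666), and the call was also lost with fry and without galacturonic acid array 2 (mean -0.38). In sulfur amino acid synthesis MET8 and MHT1 rose, by log2 differences of 2.71 and 2.09, and the mean of 26 tested genes was 0.44 (camera adjusted p = 0.0301, with an estimated correlation adjusted p = 0.665). This call was also lost with fry, under the filter at the median level, without control array 2 (mean 0.46) and without galacturonic acid array 1 (mean 0.42). The phosphate transporter PHO84 rose 5.25-fold, with 1 of 3 control arrays at the floor, and the copper transporter CTR3, the zinc-regulated ZPS1 and the external NADH dehydrogenase NDE2 fell, with log2 differences of -2.27, -1.84 and -3.02. CWP1 of the cell wall list, TSA2 and OYE3 of the oxidative stress list and the aldo-keto reductase gene YJR096W fell, with log2 differences of -2.50, -2.02, -1.80 and -2.18.

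The remaining lists did not pass. Their means ranged from -0.57 for the 6 aldo-keto reductases to 0.36 for the 16 TCA cycle genes (adjusted p = 0.187 and 0.0577). The TCA cycle list passed without galactose array 1 or 2 (adjusted p = 0.0309 and 0.0316, with 1 member higher), without control array 1 or galacturonic acid array 2 (0.013 and 0.0414), after quantile normalisation (0.0321), with array weights (0.0199) and in the fit of these 2 groups alone (0.031). With an estimated correlation the camera adjusted p of the TCA cycle list was 0.759 in the main fit and 0.517 in the fit of these 2 groups alone. The cell wall list passed with every probe set on its own (mean 0.46, adjusted p = 0.00529), and the list of gluconeogenic, glyoxylate and C2 genes without control array 3 (mean -0.49, adjusted p = 0.047). With the replicate block the cell wall, TCA cycle and ribosome biogenesis lists passed (means 0.61, 0.60 and 0.61, camera adjusted p = 0.0127, 0.0127 and 0.0182). The 20 tested genes of glycolysis averaged -0.0024, the 81 ribosomal protein genes -0.02 and the 31 ribosome biogenesis genes 0.17. Respiratory chain genes averaged 0.13, vacuolar ATPase 0.03, plasma membrane proton pump genes -0.16, multidrug resistance -0.34, cell wall 0.26 and oxidative stress -0.29. The metal and phosphate regulons averaged -0.05 for iron, -0.11 for copper, -0.23 for zinc and 0.15 for phosphate. Amino acid synthesis averaged 0.02, lipid synthesis 0.10, hypoxic genes -0.09, maltose and sucrose genes -0.03, histones and S phase -0.02, meiosis -0.08 and the other galactose pathway genes -0.11. For the iron, copper, maltose and glycolysis lists, the proton pump list and the meiosis list the mean was below 0 and the camera direction was up. For the weak acid list the mean was above 0 and that direction was down. This direction compares the test statistics of a list with those of all other genes. The medians of the other galactose pathway genes and of the histone list, 0.26 and 0.06, were above 0 while their means were below it. The members with the smallest p of lists with no member past the threshold included PGM2 (-1.31), TPO4 (-1.29), SDH4 (1.14), TRP4 (-1.04), SUT1 (1.51), ITR1 (1.00), CLN2 (1.22), UTP10 (1.07), RPS7A (1.39), PDC6 (-1.50), FRE4 (-0.96), MAL33 (-0.86), VMA1 (0.61) and SPO11 (at least 1.23-fold), as log2 differences except the last. Paralogs of ribosomal protein and MAL genes are uncertain.

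With limma, 121 of 5220 genes passed a Benjamini-Hochberg adjusted p under 0.05, 46 higher and 75 lower with galacturonic acid, and in each of the 121 both galacturonic acid arrays lay on one side of all 3 control arrays. At an unadjusted p under 0.05, 651 genes passed. The count was 774 with array weights, 58 without a filter on low genes and 77 with the filter at the median level. It also depended on the arrays in the fit: it was 256 with only the control and galacturonic acid arrays, which held 117 of the 121, and 287 or 264 without galactose array 1 or 2. It fell to 24, 3 or 10 without control array 1, 2 or 3 and to 1, which was DAK2, without either galacturonic acid array, where the lone array was assumed to vary like the other groups. Without galactose array 1 or without array 2, 6 sulfur genes were higher and 1 lower, 4 nitrogen genes were lower, and 7 or 6 beta-oxidation genes were lower. Without any one control array, at most 1 general stress, 1 MATa and 2 mating response genes and 1 to 4 Gal4 targets passed, and no beta-oxidation, sulfur, nitrogen or ergosterol gene. Without either galacturonic acid array no member of these 8 lists passed. The difference of YDL218W was -5.37 without control array 1, and that of SPG4 -2.71 or -4.25 without galacturonic acid array 1 or 2. In simulated data with the spread of these groups, 86% of 4-fold and 12% of 2-fold changes were recovered in this comparison, with 1 false call among 154. These shares hold for genes well above the floor, and recovery of dimmer genes was not tested.

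The galactose cultures were compared with the same controls as a second reference. The 4 structural galactose genes led the rises, and all 3 control arrays lay below the floor for each. GAL2 was at 1098 ± 40.3 (SD, n = 2), at least 91.5-fold higher (adjusted p = 5.21e-05), GAL10 at 605 ± 290 and at least 47.4-fold, GAL7 at 314 ± 37.8 and at least 26.0-fold, and GAL1 at 167 ± 16.6 and at least 13.9-fold higher. The 6 other Gal4 targets did not pass, with log2 differences of 0.71 ± 0.38 (SE) for GAL3, 1.49 ± 0.44 for GAL80, 1.12 ± 0.44 for GCY1, 1.01 ± 0.40 for PCL10, 0.90 ± 0.71 for FUR4 and 0.00341 ± 0.38 for MTH1. The list shifted upward (mean 2.58, camera adjusted p = 3.53e-05, with an estimated correlation adjusted p = 0.279), a call also lost under the filter at the median level. No gene of the hexose transporter and sensor list, which does not hold GAL2, passed: HXT1, HXT2, HXT3, HXT4 and HXT5 were at 0.19, -0.19, 0.30, 0.40 and -1.08, HXT6 and HXT7 at -0.58 and -0.52, HXT8 at -0.38 (at the floor on both galactose arrays and 2 of 3 control arrays), and SNF3 and RGT2 at 0.33 and -0.24. HXT1 was at the floor on 1 of 2 galactose and 2 of 3 control arrays.

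Beside the galactose genes, the largest rises were in PEX19 (6.76-fold), SNT309, SSF1, HNT3, RFA3 and PSF3 (4.55-fold). The largest falls were in YOR302W (87.3-fold, 1 of 2 galactose arrays at the floor), HAC1 (at least 36.5-fold), YNL190W, FMP45 (at least 32.0-fold), PMA2, AQY2, PUB1, the S-adenosylmethionine permease SAM3 (at least 14.5-fold), TOS6 and YFR018C. These galactose arrays were the ones with ACT1 3'/5' ratios of 19.8 and 306. Of 20 tested glycolytic genes 4 fell, PGI1, TDH3, PDC1 and ADH1, and none rose, with a list mean of -1.37 (camera adjusted p = 5.51e-07, with an estimated correlation adjusted p = 0.454). General stress genes averaged -0.71, with 7 of 30 lower, among them SOL4 and RTN2 (camera adjusted p = 1.15e-05, with an estimated correlation adjusted p = 0.454), and this call was lost without galactose array 1. Cell wall genes averaged -1.03, with TOS6 and HSP150 lower (camera adjusted p = 4.09e-05, with an estimated correlation adjusted p = 0.494). The ergosterol list averaged -0.54 with ERG2, ERG3, ERG25 and HMG1 lower, the oxidative stress list -0.53 with TSA2, OYE3 and SOD2 lower, the TCA cycle list -0.65 with no member past the threshold, and the proton pump list -1.12 with PMA2 and HSP30 lower. The camera adjusted p was 0.0136, 0.016, 0.016 and 0.026 for these lists, and with an estimated correlation the adjusted p was 0.454, 0.454, 0.537 and 0.454. These 4 calls were lost after quantile normalisation and under the filter at the median level. The proton pump and oxidative stress calls were also lost without galactose array 1, and the TCA cycle call without control array 1. In the MATa list MFA2 and ASG7 rose, by 1.54 and 1.72, and in the mating response list GPA1 and FUS1 rose, by 1.37 and 1.02, with no call for either list (adjusted p = 0.0805 and 0.408). Without galactose array 2 both lists passed, with means of 1.38 and 0.97, and the glycolysis mean was -0.73 with 0 members past the threshold. General stress genes had a larger fall without that array, with a mean of -0.99 and 4 members lower. Smaller means without it, all still passing, were -0.36 for cell wall genes with 1 member lower, -0.15 for ergosterol and -0.31 for oxidative stress with 0 members past the threshold each, -0.19 for the TCA cycle and -0.67 for the proton pump list. Without galactose array 1 the means were -1.70 for cell wall genes, -1.10 for the TCA cycle, -0.93 for ergosterol and -0.42 for general stress, with 17, 7, 10 and 11 members lower and 1 higher in each, and 14 glycolytic genes were lower. Without any one control or galacturonic acid array no member of these 5 lists passed. Further lists that passed without galactose array 2 were ribosome biogenesis (mean 1.21), the respiratory chain (-0.22), ribosomal proteins (-0.10), beta-oxidation (-0.28), hypoxic genes (-0.37) and C2 genes (-0.20). None of them passed in the main fit. There, with an estimated correlation, the camera adjusted p was 0.942 for ribosome biogenesis and 0.745 for ribosomal proteins. The hypoxic list passed also without control array 1 or 3 and under other settings, the beta-oxidation list without control array 2 or 3, the MATa list without control array 2, and the weak acid, C2 and other galactose pathway lists without control array 3. With the replicate block the ribosome biogenesis, respiratory chain, beta-oxidation, C2 and MATa lists passed too, with means of 0.73, -0.27, -0.38, -0.29 and 1.19. With every probe set on its own the fatty acid and phospholipid list passed with a mean of -1.72 (adjusted p = 2.26e-06), against -0.20 (0.246) with 1 probe set per gene. FAS1 and FAS2 supplied 16 of its 31 probe sets, and the other 15 averaged -0.20. The multidrug (-0.54), beta-oxidation (-0.59) and MATa (0.96) lists passed in that setting too, and the weak acid list (-0.33) without a filter. In lists that did not pass, the members that fell included PUT4, ILV6, TIR4, NDI1, CAR2, FIT3, POT1, MRS4, TES1, YAT1, TIR3, GRE3 and ATP3, from 11.4-fold for PUT4 to 2.40-fold for ATP3, where TIR4 is a bound of at least 8.89-fold. MHT1, INM1, KCS1 and CIT2 of these lists rose, by log2 differences of 1.79, 1.46, 1.36 and 1.30.

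In this comparison 473 genes passed, 248 higher and 225 lower, and 1813 at an unadjusted p under 0.05, while the median over all genes was 0.22 on the log2 scale. Quantile normalisation gave 131 higher and 281 lower with a median of 0.13, and scaling to the 75th percentile 100 higher and 326 lower with a median of 0.04. Weighting the arrays by their spread left 16 genes and fitting only these 2 groups left 38, while leaving out galactose array 1 or 2 gave 2145 or 191 and leaving out control array 1, 2 or 3 gave 23, 24 or 21. Leaving out galacturonic acid array 1 or 2 gave 21 or 30. In simulated data with the spread of these groups and 200 changed genes, 78 of 239 calls were false. Of the 52 called genes named by rule for this comparison, 16 had a fold that moved by over 1.50 times without galactose array 1 or 2. Of these, ADH1, ERG25, ERG3, FIT3, PGI1, RFA3, SNT309 and TOS6 lost their call without array 2, and YOR302W, YNL190W, PMA2, PUB1, PUT4, ILV6, HSP150 and NDI1 (-1.75 without array 2 and -4.53 without array 1) did not. TOS6 moved so without control array 1 too. The galactose arrays also formed a culture series of their own by their codes, so batch and group cannot be told apart.

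The third comparison set the 2 related compounds against each other. Galacturonic acid is galactose with its terminal hydroxymethyl group oxidised to a carboxyl group. The doses differed, 10 g/l against 0.23 g/l, so the values are side by side and not at matched dose. Of the 10 Gal4 targets 3 were lower with galacturonic acid and none higher, and the list did not pass (mean -0.72, camera adjusted p = 0.258, fry adjusted p = 0.0488). The 95% intervals below use 1 spread per gene, pooled over all 3 groups. The median SD between arrays was 0.17 for galacturonic acid and 0.52 for galactose, so 95% coverage is not assured. GAL10 had a log2 difference of -2.25 (95% interval -3.20 to -1.29), GAL2 of -1.97 (-2.70 to -1.23) and GAL7 of -1.50 (-2.26 to -0.74), with adjusted p of 0.0198, 0.0149 and 0.0293. GAL1 was at -0.92 (95% interval -1.68 to -0.16, adjusted p = 0.0894) and PCL10 at -1.47 (-2.46 to -0.47, adjusted p = 0.0572). GAL3, GAL80, GCY1, FUR4 and MTH1, at 0.55, -0.59, -0.46, 0.66 and 0.70, had intervals that included 0, the widest being -1.11 to 2.44 for FUR4. Within the hexose transporter and sensor list, which does not hold GAL2, no difference passed: HXT3 was at 1.29 (95% interval 0.22 to 2.35, adjusted p = 0.0899), HXT4 at 2.09 (-0.48 to 4.65), HXT5 at -0.61 (-1.97 to 0.74), HXT6 at 0.45 (-0.25 to 1.14), HXT7 at 0.29 (-0.42 to 0.99), HXT2 at 0.27 (-1.03 to 1.56), HXT1 at -0.22 (-0.88 to 0.43, with 1 of 2 arrays at the floor in each group), HXT8 at 0.26 or above (both galactose arrays at the floor, so a bound with no interval), SNF3 at -0.42 (-1.18 to 0.35) and RGT2 at 0.04 (-0.81 to 0.89).

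The mating response list was higher with galacturonic acid than with galactose, with 4 of 12 members higher, PRM1, AGA1, FIG1 and FUS1 (list mean 1.08, camera adjusted p = 0.00872, with an estimated correlation adjusted p = 0.543), a call also lost with fry and under the filter at the median level. Adjusted over the list alone, 5 members were higher and 2 lower, GPA1 at -1.15 and STE18 at -1.59. The MATa list had a mean of 1.06 with no member past the threshold (camera adjusted p = 0.0479, with an estimated correlation adjusted p = 0.543), and that call was lost under either scaling, with a floor of 1 and without galactose array 1, either galacturonic acid array or control array 3, among other settings. Glycolysis averaged 1.37 with PGI1, PDC1 and ADH1 higher, cell wall genes 1.29 with TOS6, HSP150, CIS3, PIR3, UTR2 and PST1 higher, and the TCA cycle 1.01 with SDH1, SDH4 and KGD1 higher (camera adjusted p = 6.1e-06, 4.02e-05 and 0.000941, each with an estimated correlation adjusted p = 0.543). The proton pump list averaged 0.96 with HSP30 higher (camera adjusted p = 0.0479, with an estimated correlation adjusted p = 0.543), a call lost under either scaling, with a floor of 1 or 50, without galactose array 1, without either galacturonic acid array and without control array 2, among other settings. Without galactose array 2, the array with the ACT1 ratio of 306, these 6 lists still passed with means of 0.53 for mating response (4 members higher), 0.61 for MATa, 0.73 for glycolysis (1 higher), 0.61 for cell wall (2 higher and 1 lower), 0.55 for the TCA cycle (2 higher) and 0.50 for the proton pump list (0 higher). Ribosome biogenesis (-1.04), the respiratory chain (0.35) and ribosomal proteins (0.08) also passed then. The fatty acid and phospholipid list, at 0.30 (adjusted p = 0.15), passed with every probe set on its own (1.92, adjusted p = 1.26e-06), where probe sets other than those of FAS1 and FAS2 averaged 0.33, and with the mean of all probe sets of a gene (0.69). The sulfur list passed with every probe set on its own (0.82) and with array weights (0.64), the respiratory chain with array weights (0.46) and the MATalpha list with a floor of 50 (1.96). Without galactose array 1 the means were 1.96 for cell wall and 1.63 for mating response, with 18 and 9 members higher and 1 and 3 lower. Without either galacturonic acid array no member of these 6 lists passed. Higher members of lists that did not pass included NDI1, ILV6, CYS3, PCK1, RPP2A, YAT1, QCR2, MRS4, SRX1, OPI3, TES1 and SOD2, from 13.1-fold for NDI1 to 3.88-fold for SOD2, and TIR4 was at least 6.66-fold higher. Lower members included CTT1, MET32, CTR3, PXA2, FRE4, YJR096W, DDP1, FRE1, KCS1, RLP7, YPR1, NOC2 and SAP30, from 5.82-fold for CTT1 to 2.20-fold for SAP30. The largest rises were HAC1 (at least 138-fold), AQY2, YOR302W, YNL190W, DAK2 (at least 42.8-fold), TOS6, YFR018C, SAM3, MF(ALPHA)1 (21.3-fold) and ZWF1 (18.8-fold). MF(ALPHA)1 read 142 on galactose array 1 and lay below the floor on galactose array 2, and its log2 difference was 6.19 without array 1 and 2.63 without array 2. Its call was lost without a filter (adjusted p = 0.0831), in the fit of these 2 groups alone (0.176) and without any one control or galacturonic acid array. The largest falls were YER121W (23.2-fold), ADY2 (21.8-fold), HPF1, FAT3, SPG4, PRR2, PEX19, ETR1, PIG2 and PXA1 (8.32-fold). Of these, HAC1, AQY2, YOR302W, YNL190W, TOS6, YFR018C and SAM3 were also among the largest falls with galactose against control.

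In this comparison 686 genes passed, 273 higher and 413 lower with galacturonic acid, and 1901 at an unadjusted p under 0.05, with a median over all genes of -0.24. The split was 312 higher and 227 lower after quantile normalisation and 355 higher and 181 lower after scaling to the 75th percentile. The fit of these 2 groups alone called 0 genes with limma (1250 at an unadjusted p under 0.05), and weighting the arrays left 135. Without galactose array 1 or 2 the count was 2327 or 279, without galacturonic acid array 1 or 2 it was 4 or 5, and without control array 1, 2 or 3 it was 344, 167 or 133. Of the 66 called genes named by rule for this comparison, 26 had a fold that moved by over 1.50 times without galactose array 1 or 2. Of these, CTT1, MET32, OPI3, PCK1, PGI1, PXA2, RPP2A and SPG4 lost their call without array 2, where CTT1 was at -1.34 (adjusted p = 0.104), against -3.74 without array 1. The others were YOR302W, YNL190W, TOS6, MF(ALPHA)1, ZWF1, YER121W, PRR2, ETR1, PIG2, HSP150, ADH1, QCR2, NDE2, ILV6, CYS3, GAP1, AGA1 and NDI1, which was at 2.32 without array 2 and 5.10 without array 1. ADY2 and SPG4 moved so without galacturonic acid array 1 or 2. In simulated data for this comparison 42 of 185 calls were false.

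Genes that differed from both references in the same direction numbered 72, 28 higher and 44 lower with galacturonic acid. Higher against both were DAK2, MF(ALPHA)1, SFG1, AGP1, PRM1, MET8, AGA1, FUS1, FIG1 and PHO84 among others, and lower against both were HPF1, ADY2, FAT3, SPG4, PXA1, CTR3, GAP1, JEN1 and GRE1 among others. Independent lists of these sizes would share 2.41 higher and 5.93 lower genes, and 100 simulated data sets of unchanged groups gave 0. Galacturonic acid against control called 0 genes in all 100 of those, so they set no chance level for lists of these sizes. Part of the excess over independent lists may come from the shared arrays, which are too few to be split. Scaling to the 75th percentile gave 30 higher and 29 lower. The count was 188 without galactose array 1, 13, 2 or 3 without control array 1, 2 or 3, and 1 without either galacturonic acid array. It was 0 when each comparison was fitted on its own 2 groups, since galacturonic acid against galactose then called 0.

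Between the responses to galacturonic acid and to galactose, each against control, 13 genes were higher in both and 20 lower in both, against 2.19 and 3.23 for independent lists. Unchanged groups sharing the controls gave 0, which again sets no chance level, since galacturonic acid against control called 0 genes in each simulated data set. The 13 included GAL1, GAL2, GAL7, GAL10, FUS1, MFA2, ASG7, CIT2 and MHT1, and the 20 included PMA2, RTN2, SOL4, GND2, PNC1, GRE1, TSA2 and OYE3. HTC1 and YPS3 rose with galacturonic acid and fell with galactose, and both were chosen after their values were seen. Independent lists would share 1.98 such genes, so these 2 are no excess. In the reverse direction 0 genes were called in both, against 3.56 for independent lists. Across genes the log2 differences had a Pearson r of 0.118, below the 0.273 of unchanged groups that share the controls, while their covariance was 0.0777 against 0.0349, a difference of 0.0427. The r was 0.290 without galactose array 2 and -0.00234 without galactose array 1. Part of the overlap may come from the 3 shared control arrays, which are too few to be split.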

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

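All tests in this part were chosen after the values were seen. Control probe sets, which enter no comparison, set the galactose arrays apart. The ACT1 3'/5' ratio was 19.8 on galactose array 1 and 306 on galactose array 2, against at most 1.23 on the control arrays, and the SPT15 ratio was 124 on galactose array 2, against at most 2.75. The spiked creX and bioB transcripts are added by hand and do not come from yeast. Their creX to bioB ratio was 325 on galactose array 1 and 222 on galactose array 2, against 27.2 to 38.3 on the control arrays. No floor was applied to these ratios. The bioB intensity behind 325 was 3.3, and the 5' intensities behind 306 and 124 were 10.5 and 4.1. All 3 lay below the floor of 12, so the sizes of these ratios are uncertain. The spikes also disagreed. On galactose arrays 1 and 2 bioB read 3.3 and 18.9, against 38.6 to 50.3 in control. The spiked bioC read 60 and 262, against 40.3 to 45.7 in control.

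Galactose array 2 stood apart, and for it loss of RNA from the 5' end is a candidate explanation: short genes stood 0.69 above the longer genes in their log2 shift from control, while the other 6 arrays ranged from -0.13 to 0.10. For galactose array 1 the evidence is mixed. Its ACT1 ratio of 19.8 goes with such a loss, and in 60 of 253 genes its probe sets disagreed by over 2 log2 units, against at most 6 on the control and galacturonic acid arrays, though the place of each probe set in its transcript is not given in the sources used here. However, its SPT15 ratio of 2.76 lay next to the highest control value and its short genes were 0.13 below the others, so degradation stays open there. A labelling or hybridisation batch cannot be told apart from the group, because the 2 arrays with the highest creX to bioB ratios were also the 2 galactose arrays. The effect of galactose itself remains an open explanation for any difference outside the GAL genes.

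Probe sets without a listed gene also held signal. Of 772 such probe sets above the floor, 13 were higher with galacturonic acid than in control and 0 lower, in a limma fit of every probe set. With galactose 64 were higher and 26 lower than in control, and with galacturonic acid 35 were higher and 51 lower than with galactose. Their genes are not named here.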

How the results depend on the processing

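The count over genes of at least 500 bases was chosen after the data were seen; the other alternatives were set before. In the order galacturonic acid against control, galactose against control, galacturonic acid against galactose, and both references, 121, 473, 686 and 72 genes passed. Without a filter on low genes the counts were 58, 178, 244 and 35, and with a filter at the median level 77, 120, 153 and 33, where fewer dim genes were tested. Array weights gave 774, 16 and 135, and 64 against both references. Fitting only the groups compared gave 256, 38, 0 and 0 genes, with fewer degrees of freedom; at an unadjusted p under 0.05 the third comparison had 1250. An adjusted p under 0.01 left 23, 25, 49 and 8. Leaving out one array gave 1 to 287, 21 to 2145, 4 to 2327 and 1 to 188. The correlation of the responses ranged from -0.00234 to 0.290 when one array was left out, against 0.118. Genes of at least 500 bases gave 106, 391, 588 and 63. The cause was not tested beyond the smaller designs named.

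Arrays sharing the last number of a label field were set as a replicate block. The galacturonic acid and galactose arrays both carry the numbers 1 and 2, and every control array carries 1. With 2 arrays per group their deviations mirror each other and give 1 correlation across genes, 0.17, and the samples share only a number. The block gave 112, 69 and 1189 genes, 91 against both references, and 10, 14 and 6 lists.

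Gene lists called were 9, 8 and 6. An estimated correlation called 0 in each comparison with camera (6, 2 and 1 at an unadjusted p under 0.05), and fry called 5, 1 and 1. For galactose against control, quantile normalisation called 4 lists, the median filter 3, and leaving out one array 5 to 16; the median filter called 3 lists for galacturonic acid against galactose. The Gal4, general stress, beta-oxidation and MATa lists of galacturonic acid against control lost their call only with an estimated correlation, among all alternatives run; the mating response list lost it also under the median filter. Over all alternatives, called lists kept their call in 420 values and lost it in 86, and called named genes kept it in 2117 and lost it in 1035; none changed direction while called. These counts leave out named genes that a setting did not test, as under the filter at the median level. DAK2 passed for galacturonic acid against control in every alternative in which it was tested. Intensities near the floor of 12 limit what can be read for 31.1% to 33.8% of probe sets.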

Other observations

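All tests and genes in this part were chosen after the data were seen. FIG2, a cell wall adhesin of mating cells, was higher by log2 differences of 2.23 against control and 2.08 against galactose, and the pheromone-regulated PRM6, below the floor on all 3 control arrays, was at least 1.81-fold higher than control. YGR109W-B, an open reading frame of a Ty3 retrotransposon, was higher with galacturonic acid by 2.28 and with galactose by 1.70 than in control. COS10 and COS12, of the subtelomeric COS family whose members are similar in sequence, so that probes cannot always separate them, were higher than control, COS10 by 2.28 on the log2 scale and COS12 at least 2.70-fold from below the floor. Both were also higher than with galactose. The transporter gene BIO5 and the sulfite pump gene SSU1 fell against control, with log2 differences of -1.43 and -2.02.

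The rise of the GAL genes with galacturonic acid may reflect a smaller amount of galactose brought in with the galacturonic acid. For 4 of the 4 structural genes, GAL1, GAL2, GAL7 and GAL10, the mean lay between control and galactose. Less galactose than 0.23 g/l would give this order if the response grows with dose, but no smaller dose was measured. GAL1 did not differ from galactose past the threshold (limma adjusted p = 0.0894). Among the other Gal4 targets, GAL80 and GCY1 also lay between, GAL3, FUR4 and MTH1 lay above galactose, and PCL10 lay below control. None of these others differed from galactose past the threshold. The galactose means rest on the 2 arrays with raised ACT1 3'/5' ratios. The galactose content of the galacturonic acid and the reason for the 0.23 g/l dose are not given in the sources used here. If 0.23 g/l were the amount brought in, the galactose group would match it and galactose alone would not give lower means with galacturonic acid. A weak action of galacturonic acid itself could give the same order, and no array here separates them.

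The rise of mating genes has as a candidate explanation MATalpha cells in the galacturonic acid cultures, whose pheromone would act on the MATa cells. Of 4 MATalpha genes, 2 lay on both galacturonic acid arrays above every control array and the floor: MF(ALPHA)1 (912 and 845) and STE3 (72.5 and 73.8). On galactose array 1, MF(ALPHA)1 read 142 and STE3 51.4, also above every control array, against 11.9 and 15.6 on galactose array 2. SAG1 read 28.1 and 49.6 with galacturonic acid and 40.4 and 60.3 with galactose, against 31.4 to 33.0 in control, and MF(ALPHA)2 was at the floor on all arrays. Another 2 probe sets are each listed for MATALPHA1 and HMLALPHA1 together, so they entered no gene-level fit. The first read 2.0 and 1.2 with galacturonic acid and 0.7 and 3.7 with galactose, against 0.4 to 2.2 in control. The second read 14.0 and 12.3 with galacturonic acid and 14.1 and 55.3 with galactose, against 9.1 to 9.5 in control. No value here gives the level of any of these transcripts in MATalpha cells, so the explanation stays open beside a response of MATa cells.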
